A study of Mus musculus with 32 samples.

How the data were processed

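Total RNA from the striatum of male mice was labelled with biotin and hybridised to an Affymetrix mouse expression array, per the labels' protocols. There were 32 arrays, and each was treated as a separate mouse, since the labels give no identifiers of animals. The labels name a kit for in vitro transcription from the 3' end, so signal depends on RNA integrity. They also say that mice were dosed in the afternoon and, in general, dissected near the end of the light phase. The deposited values are on a log2 scale as the range of values shows (2.15 to 14.7), and the authors had normalized them between arrays, with array medians within 5.73 to 5.78. The normalization method is not given in the sources used here. The authors' description names the RACE software for quality control only.

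The matrix held 45101 probe sets, of which 64 were controls and were used for quality alone. Gene symbols came from the platform's probe list and a mouse gene table. Of the probe sets other than controls, 34945 had 1 symbol, 932 had several and 9160 had none. Of the single-gene probe sets, 204 had a gene identifier that was not found in the gene table and kept the platform's symbol. Each gene was represented by its single-gene probe set with the highest mean value over all arrays, giving 18193 genes, 9010 of them with more than 1 probe set. No filter on low values was applied.

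Arrays were grouped by genotype and treatment as the labels give them: 7 wild-type vehicle, 10 wild-type HSP990, 7 R6/2 vehicle and 8 R6/2 HSP990. A linear model of the 4 group means was fitted to the log2 values with limma 3.58.1 in R 4.3.3 and data.table (version 1.17.8), with its moderated two-sided test. The 5 comparisons were HSP990 against vehicle in each genotype, R6/2 against wild type on each treatment, and the interaction, which is the R6/2 response minus the wild-type response. P-values were adjusted by Benjamini and Hochberg over the genes of a comparison, and a gene was called at an adjusted p under 0.05. The comparisons of the genotypes under vehicle and under HSP990 share no arrays, nor do the treatment comparisons. Log2 changes are given with the standard error of the fit, and fold changes are their antilogs. That error rests on a spread per gene shared by all 4 groups, so it can be too small where the groups compared vary more.

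There were 23 gene lists with 472 entries, of which 435 were measured: heat shock, co-chaperone and chaperonin, unfolded protein response, immediate early, glucocorticoid-responsive, NRF2, proteasome, cholesterol synthesis, clock, respiratory chain, histone and chromatin, and synaptic channel genes, and markers of medium spiny neurons, interneurons, cortex, choroid plexus, neighbouring subcortical regions, astrocytes, myelin, oligodendrocyte precursors, microglia, endothelium and red blood cells. The 472 entries are 462 distinct genes, since some genes stand in more than 1 list. Lists were tested with camera at its preset correlation of 0.01, which compares a list with the other genes, and again with the correlation estimated from the residuals. Adjusted p of lists were taken over the 23 lists of a comparison. Members were counted both with adjustment over all genes and adjusted over the list alone. The test fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes, was an alternative. The size of the heat shock response in R6/2 relative to wild type was the slope through the origin over members that rose in wild type, with a 95% interval from 10000 bootstrap resamples of arrays within groups.

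The lists, the tests, the rule for named genes and most alternatives were chosen before the data were examined. The rule names the 10 largest rises and 10 largest falls among called genes (5 and 5 for the genotypes on HSP990), the 10 interaction genes with the smallest adjusted p, up to 4 members of each list with the smallest p, any heat shock list member, and Htt and Hsf2 throughout. Another heat shock factor gene of the rule is not reported here. Symbols that are only clone or predicted-gene names were passed over. Where a count of a list was 5 or fewer, members that the rule did not name are named in the text, and these names were chosen after their values were seen.

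Alternatives were quantile normalization, median centring of arrays, removal of dim probe sets, the mean of the probe sets of a gene, all probe sets, only the groups compared, a trended and robust variance, array weights, replicate number as a block, the leading component of the residuals as a covariate, and each array left out in turn. After the data were seen, 4 alternatives were added: the 3' bias of each array (the mean of the 3' minus 5' differences of Gapdh and Actb control probe sets) as a covariate, the removal of the 2 arrays with a Gapdh difference over 2, the heat shock slope over members called for the response averaged over both genotypes, and the heat shock ratio with members weighted by the averaged response in 1 part of the arrays and measured in the other part (50 random divisions of each group into 2 parts of near equal size). The last was also taken over genes outside the chaperone lists, and its interval comes from a jackknife over the measured arrays. The fit was also tested on simulated data: with changes of 0.5, 1 and 2 log2 units added to 50 genes each, 84%, 96% and 98% were recovered for HSP990 in wild type and 50%, 86% and 94% for the interaction, and for 0.25 log2 units 20% and 4%. The simulated noise was independent between genes and arrays, without structure shared by whole arrays, so recovery in the real data may differ. No array was left out of the reported fit.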

Results

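Expression was measured with 32 arrays in the striatum of male mice, 12 weeks old, on a mixed CBA and C57Bl/6 background. The R6/2 line carries a fragment of the human huntingtin gene and is used as a mouse model of Huntington's disease. Wild-type and R6/2 mice received vehicle or NVP-HSP990, an oral inhibitor of the chaperone HSP90. The design text of the series gives 12 mg/kg and 4 h, which the labels of single arrays do not repeat. There were 7 wild-type vehicle, 10 wild-type HSP990, 7 R6/2 vehicle and 8 R6/2 HSP990 arrays. Median log2 values of the arrays ran from 5.73 to 5.78, and the number of arrays limits the precision of each group mean. The labels give replicate numbers but no identifiers of animals, so the p-values measure the spread between these samples. In all comparisons 18193 genes were tested.

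The response of wild-type mice to HSP990 addresses which transcripts the inhibitor moves in mice without the transgene. Hspa1b and Hspa1a, which encode inducible chaperones of the HSP70 family, rose 44-fold and 39.7-fold (log2 changes of 5.46 ± 0.29 and 5.31 ± 0.19, SE, n = 10 treated and 7 vehicle arrays). The sequences of these genes are nearly identical, so their probe sets can share signal. On vehicle the mean of Hspa1a (5.88) was close to the median of all probe sets (5.77), so its fold is less certain. Hspb1, a small heat shock protein gene, rose 6.71-fold (2.75 ± 0.12), and Dnajb1, which encodes an HSP40 co-chaperone, rose 3.34-fold (1.74 ± 0.08). Hspe1 and Hspd1, which encode the mitochondrial chaperonin, rose 2.46-fold (1.30 ± 0.08) and 2.23-fold (1.16 ± 0.08). Of the 27 measured genes of the heat shock list, 22 rose and none fell (24 rose when adjusted over the list alone). The heat shock list gave adjusted p = 1.06e-77, and adjusted p = 1.49e-08 with an estimated correlation. The other 5 members, Dnajb5, Dnajb6, Hspa1l, Hspa4 and Hspb8, had log2 changes between -0.19 and 0.32.

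**Figure D1:**
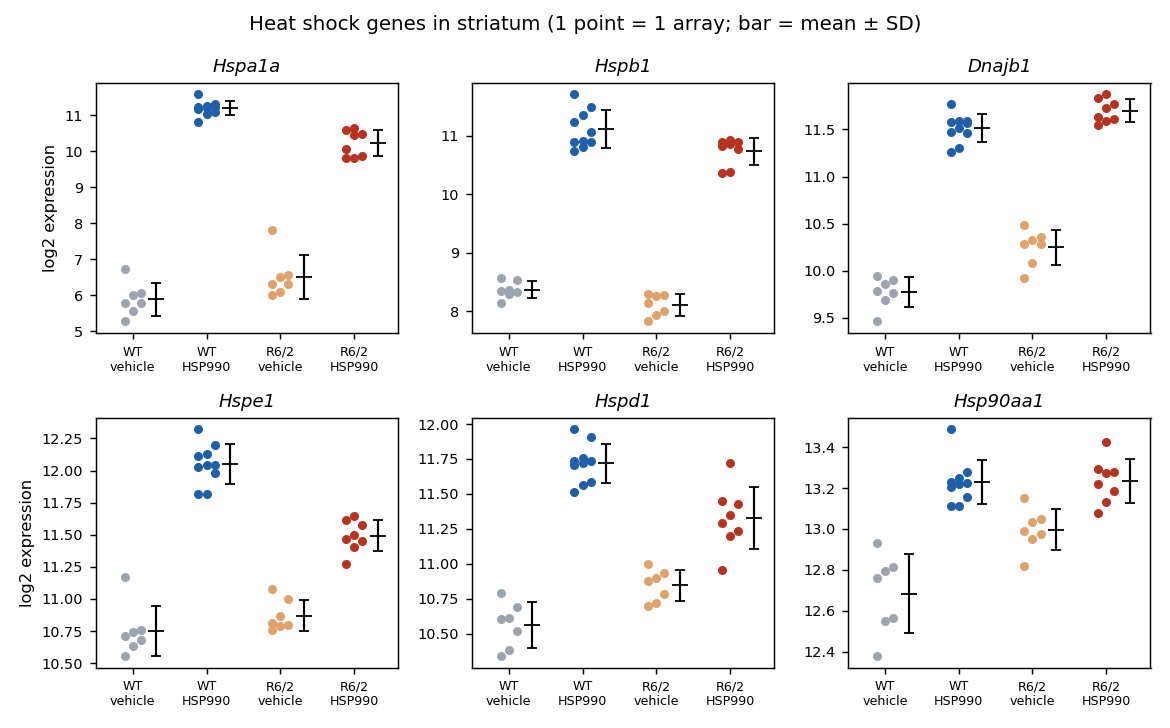
Log2 expression of heat shock genes in each array, by genotype and treatment, where each point is 1 array and the bar is the mean ± SD. For Hspa1a the group means are 5.88 (wild type, vehicle), 11.19 (wild type, HSP990), 6.51 (R6/2, vehicle) and 10.21 (R6/2, HSP990).

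HSP90 co-chaperone genes rose with them. Of 19 measured members of the co-chaperone and chaperonin list, 11 rose, among them Chordc1 (2.37-fold, log2 1.25 ± 0.10), Fkbp4 (2.05-fold, 1.03 ± 0.08), Ahsa1 (1.89-fold, 0.92 ± 0.10) and St13 (1.48-fold, 0.57 ± 0.06), and 14 rose when adjusted over the list alone. The only member that fell was Fkbp5, a steroid receptor co-chaperone gene that glucocorticoids induce (log2 -0.74 ± 0.16). The list test gave adjusted p = 6.43e-25 (adjusted p = 9.83e-06 with an estimated correlation). Several of these genes are also members of the heat shock list, so the lists are not independent. Outside the chaperones, the largest rises were in Neat1, a nuclear long noncoding RNA (3.96-fold, 1.99 ± 0.42), Rab39 (3.45-fold, 1.79 ± 0.14), Cyp2s1 (3.06-fold, 1.61 ± 0.16), Smco3 (3.01-fold, 1.59 ± 0.31) and the immediate early gene Jun (2.64-fold, 1.40 ± 0.21). For Neat1 only 1 of 2 probe sets moved in this direction.

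Genes that glucocorticoids induce in the brain fell in wild-type mice. Of 24 measured members, 12 fell and none rose (17 fell when adjusted over the list alone). Zbtb16, Plin4 and Sult1a1 fell by 1.38 ± 0.31, 1.38 ± 0.33 and 1.31 ± 0.28 on the log2 scale, and Nfkbia, an inhibitor of NF-kappa-B, and the lipid transporter gene Mfsd2a fell by 1.17 ± 0.13 and 1.15 ± 0.11. The list test gave adjusted p = 2.55e-16, but adjusted p = 0.0647 with an estimated correlation. Wild-type vehicle replicate 4 stood apart, with a list mean of 9.56 against 8.14 to 8.58 in the other vehicle arrays. Without it 12 members fell and the mean log2 change was -0.49 (adjusted p = 7.08e-11, and adjusted p = 0.0907 with an estimated correlation). Other large falls were in Crh, the gene of corticotropin-releasing hormone (-1.92 ± 0.47), the transcription factor genes Klf2 (-1.58 ± 0.11) and Klf4 (-1.21 ± 0.10), and Mpp7 (-1.24 ± 0.25) and Plekhf1 (-1.13 ± 0.13).

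Smaller groups moved in part. Among clock genes Per1, Per2 and Ciart fell by 0.67 ± 0.11, 0.62 ± 0.18 and 0.77 ± 0.13, and Npas2 rose by 0.31 ± 0.09, of 18 measured. When adjusted over the list alone 1 rose and 4 fell (list test adjusted p = 0.137). Among cholesterol synthesis genes Mvd, Fdft1, Tm7sf2 and Stard4 fell, by 0.61 ± 0.09, 0.68 ± 0.11, 0.42 ± 0.09 and 0.45 ± 0.11, and the other 16 of 20 did not pass. When adjusted over the list alone 4 fell (adjusted p = 0.0515). In the list of the unfolded protein response, Atf4, Chac1, Ddit3 and Trib3, which act in the integrated stress response, rose, while Xbp1, Manf and Sdf2l1 fell, of 24 measured. When adjusted over the list alone 4 rose and 7 fell (adjusted p = 0.874). Of 26 immediate early genes, Jun, Arc, Atf3, Ccn1 and Gadd45b rose and Klf4 and Dusp6 fell (7 and 4 when adjusted over the list alone; list test adjusted p = 0.136). Of 15 targets of the oxidative stress factor NRF2, Gclc and Slc7a11 rose (4 rose and 1 fell when adjusted over the list alone). The NRF2 list gave adjusted p = 0.00424, but adjusted p = 0.187 with an estimated correlation.

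In total 1056 genes changed with HSP990 in wild-type mice, 407 up and 649 down, of which 28 rose and 15 fell at least 2-fold. Every one of the 10 treated arrays lay beyond the vehicle mean for each of the 10 largest rises and 10 largest falls. These genes were chosen on the same arrays, and the 2 groups did not overlap for 8 of the 10 rises and 8 of the 10 falls. Rab39, Crh, Klf2, Klf4, Atf3 and Trib3 are dim, with a mean value at or below the median of all probe sets (5.77), so their folds are less certain. Myelin genes were higher as a list (14 measured, none passing over all genes and 3 higher when adjusted over the list alone; adjusted p = 0.000144). So were proteasome subunits (31 measured, none passing in either count; 0.00456) and medium spiny neuron genes (27 measured, none passing in either count; 0.0423). With an estimated correlation none of the 3 held (adjusted p = 0.527, 0.527 and 0.759). Respiratory chain subunits were lower (2 of 32, Cox7a2 and Ndufb8, fell, and 2 when adjusted over the list alone). The respiratory chain list gave adjusted p = 0.00424, but adjusted p = 0.527 with an estimated correlation. Without wild-type vehicle replicate 5, whose RNA showed the strongest 3' bias of that group, the proteasome list did not pass (adjusted p = 0.0969). The call of the medium spiny neuron list was lost with the removal of any of 9 arrays (adjusted p = 0.051 to 0.213). The call of Crh was lost with replicate number as a block (adjusted p = 0.0626), a fit that called 655 genes.

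The response of R6/2 mice to HSP990 addresses whether the same transcripts move in the disease model. Hspa1b and Hspa1a rose 26.5-fold and 13-fold (log2 changes of 4.73 ± 0.30 and 3.70 ± 0.20, SE, n = 8 treated and 7 vehicle arrays), Hspb1 rose 6.21-fold (2.63 ± 0.12) and Dnajb1 rose 2.73-fold (1.45 ± 0.08). Of the 27 measured heat shock genes, 21 rose and none fell (22 rose and 1 fell when adjusted over the list alone). Here the heat shock list gave adjusted p = 2.64e-42, and adjusted p = 6.11e-06 with an estimated correlation. Without R6/2 vehicle replicate 7, in which Hspa1a was at 7.82 against 6.01 to 6.57 in the other 6 vehicle arrays, 17 members rose. Of 19 co-chaperone and chaperonin genes, 11 rose and none fell (13 rose when adjusted over the list alone), with Chordc1 at 0.78 ± 0.10, Fkbp4 at 0.68 ± 0.09, Ahsa1 at 0.65 ± 0.10 and St13 at 0.34 ± 0.06. The co-chaperone list gave adjusted p = 1.53e-12, and adjusted p = 0.0016 with an estimated correlation. Rab39 (3.84-fold, 1.94 ± 0.15), Cyp2s1 (2.82-fold, 1.49 ± 0.17), the cytokine gene Tnfsf9 (2.34-fold, 1.22 ± 0.10), Jun (2.15-fold, 1.10 ± 0.22), Swt1 (2.09-fold, 1.07 ± 0.09) and Dedd2 (2.06-fold, 1.04 ± 0.10) were the other large rises.

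Among genes that fell in R6/2 mice were Klf2 and Klf4 (log2 -1.07 ± 0.12 and -1.01 ± 0.10) and the glucocorticoid-responsive genes Zbtb16, Nfkbia, Mfsd2a and Per1 (-1.27 ± 0.32, -0.67 ± 0.13, -0.66 ± 0.11 and -0.60 ± 0.12). Of the 24 glucocorticoid-responsive genes 8 fell and none rose (10 fell when adjusted over the list alone). The list gave adjusted p = 3.4e-12, but adjusted p = 0.166 with an estimated correlation. Without wild-type vehicle replicate 4, an array outside this comparison that enters the variance of the fit, adjusted p = 0.0275 with an estimated correlation, with 8 falls as before. Markers of medium spiny neurons, the main striatal neurons, fell with HSP990 in 2 cases, Gpr6 (-1.01 ± 0.22) and the dopamine receptor gene Drd1 (-0.80 ± 0.16). The other 25 of 27 did not pass, and 2 fell when adjusted over the list alone (list test adjusted p = 0.459). Of 24 measured members of the unfolded protein response list, Xbp1, Manf and Hspa5 fell (-0.53 ± 0.07, -0.45 ± 0.09 and -0.32 ± 0.08), as did Pdia6 and Sdf2l1. Chac1, which encodes an enzyme that degrades glutathione, rose (0.92 ± 0.15). The counts of 5 and 1 were the same when adjusted over the list alone (adjusted p = 0.00964, but adjusted p = 0.169 with an estimated correlation). Htr4 (-1.17 ± 0.30, 1 of 2 probe sets in this direction), Pcdh20 (-0.88 ± 0.25), Kcnv1 (-0.87 ± 0.17), Rprml (-0.83 ± 0.19) and Car7 (-0.79 ± 0.16) also fell.

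In total 563 genes changed with HSP990 in R6/2 mice, 396 up and 167 down, of which 13 rose and 5 fell at least 2-fold. All 8 treated arrays lay beyond the vehicle mean for each of the 20 largest changes, genes that were chosen on the same arrays. The 2 groups did not overlap for 9 of the 10 largest rises but for only 3 of the 10 largest falls. Dim by the same measure were Rab39, Tnfsf9, Htr4, Klf2, Klf4 and Hspa1l. Of 18 clock genes Per1 fell, and 2 fell when adjusted over the list alone (list test adjusted p = 0.0426, but adjusted p = 0.307 with an estimated correlation). This call was lost without R6/2 HSP990 replicate 2, 5 or 8 (adjusted p = 0.0619, 0.0698 and 0.0897) or R6/2 vehicle replicate 5 or 7 (0.0912 and 0.285). The count of genes was 309 without R6/2 vehicle replicate 7 and 1043 without R6/2 vehicle replicate 1, 202 from a fit of these groups alone and 368 with the 3' bias of each array as a covariate. In the fit of these groups alone the calls of Drd1, Gpr6, Htr4, Jun and Car7 were lost (adjusted p = 0.0642, 0.123, 0.14, 0.0636 and 0.0597), as was that of Pcdh20 (0.228). That fit also lost 6 of the 21 heat shock calls: Cryab, Dnajb4, Hspa1l, Hspa4l, Hspa8 and Hspa9 (adjusted p = 0.0643, 0.104, 0.0834, 0.0835, 0.166 and 0.0788). With the removal of single arrays the calls of Cryab, Dnajb4, Hspa1l and Hspa8 were lost in 9, 7, 13 and 16 cases (0.0501 to 0.14 for Hspa8). The mean of the probe sets of a gene ended the calls of Dnajb4, Hspa9, Jun, Pcdh20 and Zbtb16 (0.334, 0.0757, 0.234, 0.153 and 0.0513). The 3' covariate ended those of Cryab, Hspa1l, Hspa8, Htr4, Pcdh20 and Zbtb16 (0.1, 0.154, 0.133, 0.0556, 0.1 and 0.0707). Without the 2 arrays of strong 3' bias those of Dnajb4, Hspa1l, Hspa8 and Pcdh20 ended (0.0584, 0.084, 0.0546 and 0.0543). With replicate number as a block Cryab, Dnajb4, Hspa8 and Pcdh20 did not pass (0.0571, 0.0544, 0.0902 and 0.077), with quantile normalization Hspa1l and Hspa8 (0.0506 and 0.0824), and with array weights Cryab (0.0545). The call of Zbtb16 was lost without R6/2 HSP990 replicate 1 or R6/2 vehicle replicate 7 (0.0505 and 0.0843), and that of Pcdh20 with the removal of any of 14 arrays (0.05 to 0.0824).

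The genes that responded overlapped between the genotypes. Of the 407 genes that rose in wild type, 132 also rose in R6/2 (8.86 would be shared by independent lists of these sizes), and 68 fell in both (5.96 for independent lists). A further 2 and 4 genes moved in opposite directions. Both comparisons use the same estimate of the spread of each gene, so the counts for independent lists are a low baseline. Across all genes the log2 changes correlated with r = 0.413, and over the 1056 genes called in wild type with r = 0.825, where genes are not independent replicates and the genes were chosen on the wild-type values.

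The interaction between genotype and treatment tests whether HSP990 moved a gene differently in R6/2 and wild-type mice. Heat shock genes rose less in R6/2, with a difference of log2 changes of -1.61 ± 0.28 for Hspa1a, -0.68 ± 0.11 for Hspe1 and -0.67 ± 0.12 for Hspd1 (R6/2 minus wild type, SE, n = 7 to 10 arrays per group). All 22 heat shock genes that rose in wild type had a smaller log2 change in R6/2, 3 of them past the test over all genes and 12 when adjusted over the list alone. The list test of the interaction gave adjusted p = 6.55e-19 (adjusted p = 0.00271 with an estimated correlation). The slope of the R6/2 response on the wild-type response over these 22 genes was 0.760 (95% bootstrap interval 0.668 to 0.855). It was 0.713 (0.614 to 0.815) without Hspa1a and Hspa1b. The 22 genes were chosen on their wild-type changes, which favours a smaller value in R6/2. Over all 27 measured members, weighted in 1 part of the arrays and measured in the other, the ratio was 0.771 (0.668 to 0.874). Hspb1 and Hspa9 kept 96% and 97.4% of the wild-type log2 change, against 47.8% for Hspe1 and 41.9% for Hspd1.

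**Figure D2:**
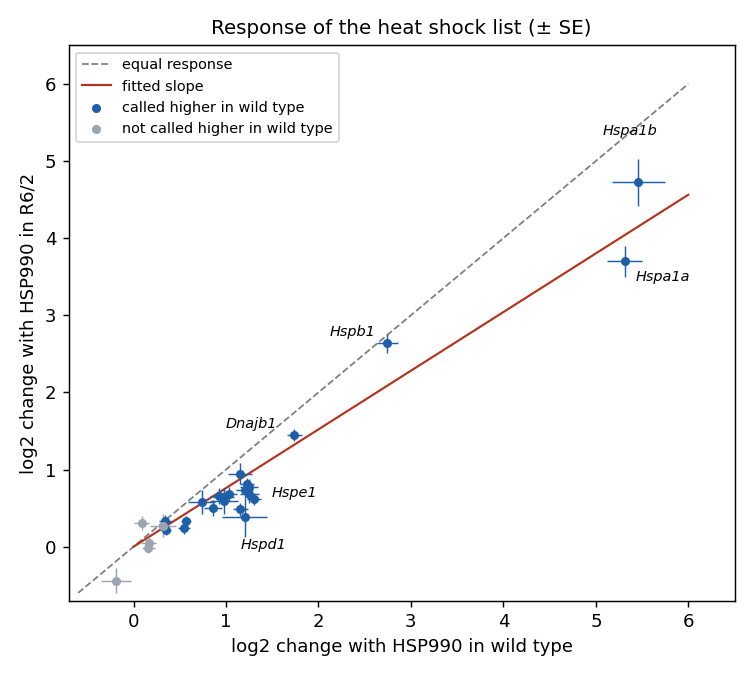
Log2 change with HSP990 in R6/2 (vertical axis) against wild type (horizontal axis) for the 27 measured heat shock genes, ± SE, with lines for an equal response and for the fitted slope of 0.760. The 22 genes called higher in wild type lie below the line of equal response.

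Other genes moved in opposite directions in the genotypes. Cenpe, which encodes a kinetochore motor protein, fell in wild type and rose in R6/2 (log2 -0.34 ± 0.08 and 0.54 ± 0.09; difference 0.88 ± 0.12, adjusted p = 0.000359). The kinase gene Mknk2 (-0.32 and 0.27; difference 0.60 ± 0.09) and Tcf19 (-0.41 and 0.64; 1.06 ± 0.18) did the same, and the potassium channel subunit gene Kcns2 rose in wild type and fell in R6/2 (0.33 and -0.41; -0.74 ± 0.11). Rad51ap1, a DNA recombination gene (0.86 in R6/2; difference 0.93 ± 0.16), and Chek1, a DNA damage checkpoint kinase gene (0.50 in R6/2; 0.66 ± 0.12), rose in R6/2, with wild-type values of -0.07 and -0.16 that did not pass. Sap30, a subunit of a histone deacetylase complex, fell 2-fold in wild type (SE 0.08 on the log2 scale), with a value of -0.26 in R6/2 that did not pass (difference 0.74 ± 0.12).

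**Figure D3:**
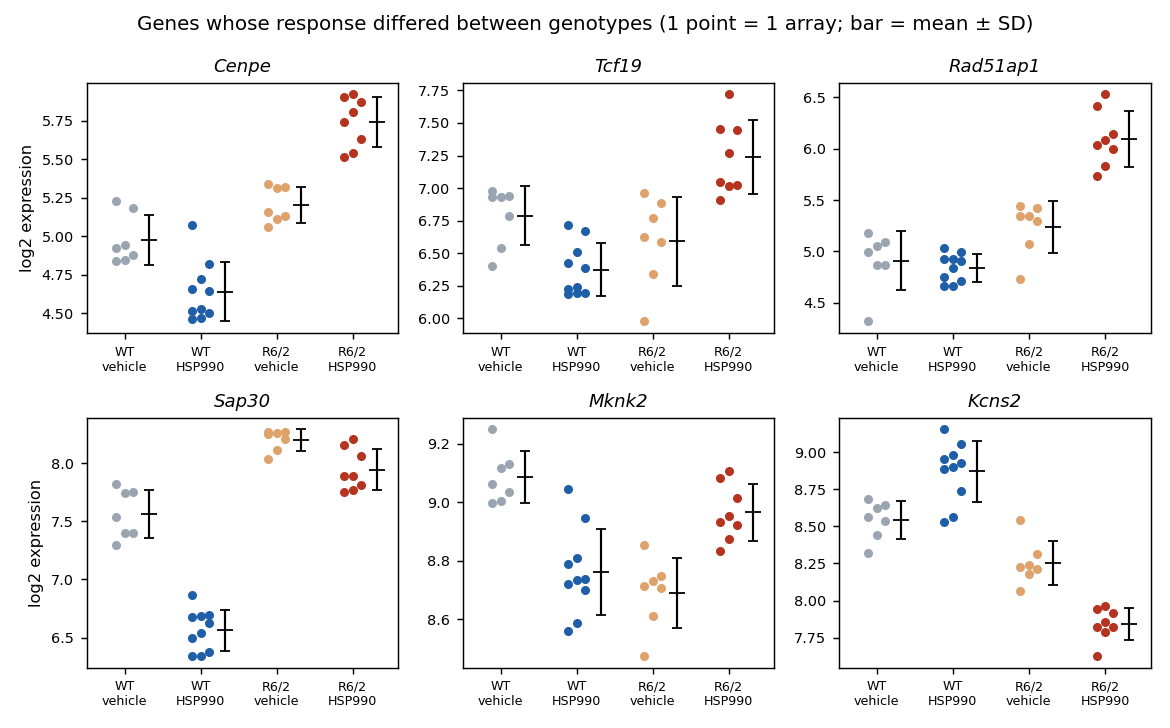
Log2 expression in each array of genes whose response to HSP990 differed between the genotypes, where each point is 1 array and the bar is the mean ± SD. Cenpe fell by 0.34 with HSP990 in wild type and rose by 0.54 in R6/2.

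In total 45 genes passed the interaction test, 31 with a higher and 14 with a lower change in R6/2. Cenpe, Chek1 and Rad51ap1 are dim genes. Co-chaperones as a list also rose less in R6/2 (adjusted p = 1.86e-05, but adjusted p = 0.092 with an estimated correlation; 4 of 19 lower when adjusted over the list alone). Lower interactions of immediate early, myelin and synaptic channel genes (adjusted p = 0.00391 for each list) and of medium spiny neuron and unfolded protein response genes (0.00988 for both) had no member past the test over all genes. With an estimated correlation these gave adjusted p = 0.613, 0.739, 0.476, 0.739 and 0.297. When adjusted over the list alone, 1 immediate early, 2 medium spiny neuron and 1 unfolded protein response member were lower, 1 synaptic member was higher and no myelin gene passed. Without R6/2 vehicle replicate 7 the immediate early and synaptic lists did not pass (adjusted p = 0.0715 and 0.0583), without R6/2 vehicle replicate 5 the myelin list did not (0.0677), and the medium spiny neuron list was lost with the removal of any of 5 arrays (0.0598 to 0.166). The count of 45 became 182 without R6/2 vehicle replicate 1, 93 without wild-type vehicle replicate 7, 76 without wild-type HSP990 replicate 2, 69 without R6/2 HSP990 replicate 2, 69 without wild-type vehicle replicate 4 and 30 without wild-type vehicle replicate 1. It was 25 without the 2 arrays of strong 3' bias and 16 with that bias as a covariate, where Chek1 was lost (adjusted p = 0.0804). With the mean of the probe sets of a gene the calls of Chek1 and Cenpe were lost (0.0773 and 0.139).

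R6/2 mice on vehicle were compared with wild-type mice on vehicle to describe the disease model without the drug. Genes of medium spiny neurons were lower: Scn4b, a sodium channel subunit gene, was 6.91-fold lower (log2 -2.79 ± 0.26, SE, n = 7 and 7 arrays), Rgs9 3.69-fold lower (-1.88 ± 0.19), the adenylyl cyclase gene Adcy5 3.18-fold lower (-1.67 ± 0.15) and the phosphodiesterase gene Pde1b 2.86-fold lower (-1.52 ± 0.15). Of 27 measured members 26 were lower, and Tac1 was the member that did not pass (-0.37 ± 0.15), while all 27 were lower when adjusted over the list alone. The medium spiny neuron list gave adjusted p = 4.76e-31, and adjusted p = 0.0129 with an estimated correlation. Of 25 ion channel and receptor genes of the synapse 18 were lower and none higher (20 lower when adjusted over the list alone), with Gabrd at -1.59 ± 0.16, Htr1d at -1.12 ± 0.15 and Kcnt1 at -0.66 ± 0.08. The synaptic list gave adjusted p = 1.87e-13, and adjusted p = 0.00649 with an estimated correlation. Striatal interneuron markers were lower as well, 6 of 14 over all genes and over the list alone, among them Npy (-0.94 ± 0.11), Th (-0.91 ± 0.14), Nos1 (-0.70 ± 0.10) and Slc18a3 (-0.70 ± 0.13). The interneuron list gave adjusted p = 0.000495 (adjusted p = 0.00649 with an estimated correlation).

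**Figure D4:**
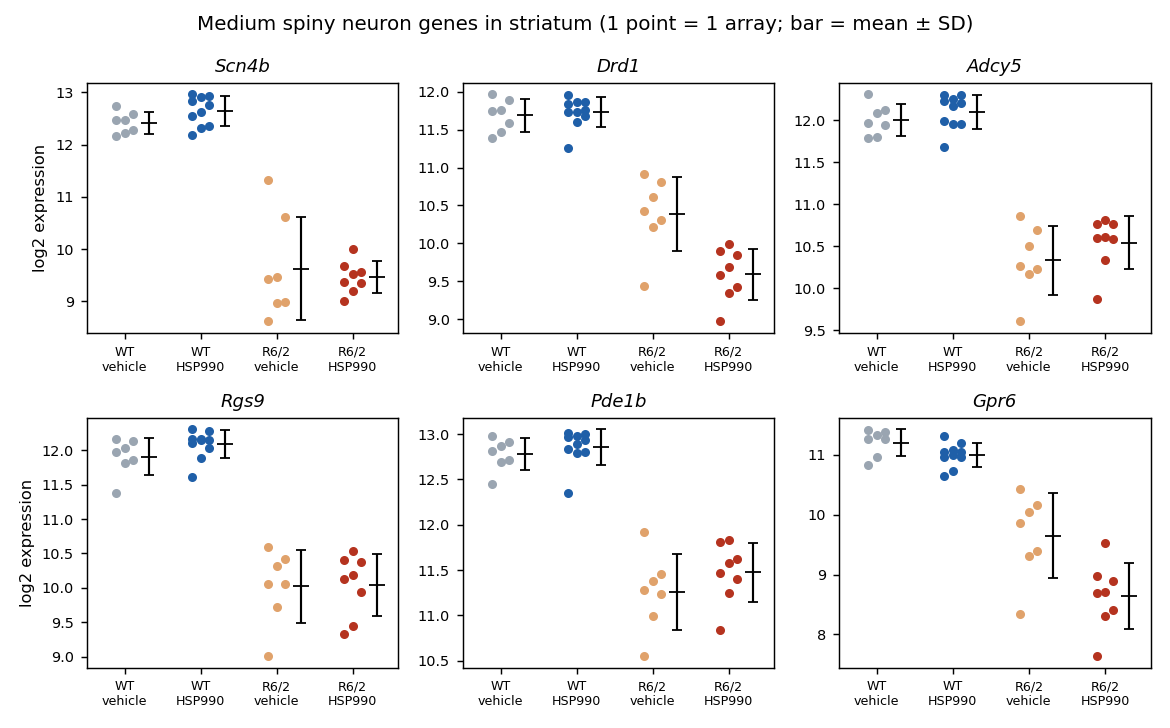
Log2 expression in each array of genes of medium spiny neurons, by genotype and treatment, where each point is 1 array and the bar is the mean ± SD. For Scn4b the R6/2 arrays lie below all wild-type arrays on vehicle, by a mean of -2.79, and on HSP990, by a mean of -3.18.

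Clock genes were lower in R6/2 on vehicle: Ciart by 2.9-fold (log2 -1.54 ± 0.14), Dbp by 2.58-fold (-1.37 ± 0.15), Npas2 by 2.26-fold (-1.18 ± 0.10) and Hlf by 2.25-fold (-1.17 ± 0.16). Of 18 clock genes 10 were lower and Nfil3 was higher (11 lower and 2 higher when adjusted over the list alone). The clock list gave adjusted p = 2e-06, and adjusted p = 0.00649 with an estimated correlation. Of 31 proteasome subunits 17 were higher and none lower, by small amounts such as 0.47 ± 0.08 for Psmc6 and 0.41 ± 0.05 for Psma2 (18 higher when adjusted over the list alone). The proteasome list gave adjusted p = 2.74e-08, and adjusted p = 0.0412 with an estimated correlation. Immediate early genes were lower in 10 of 26 cases (12 when adjusted over the list alone), among them Nptx2 (-1.33 ± 0.24), Egr3 (-0.86 ± 0.13), Homer1 (-0.71 ± 0.11) and Dusp1 (-0.55 ± 0.10). The immediate early list gave adjusted p = 2.13e-05, but adjusted p = 0.14 with an estimated correlation.

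Some chaperone genes were higher in R6/2 mice on vehicle. Of 27 heat shock genes 11 were higher, among them Ahsa2 (0.95 ± 0.12), Dnajb1 (0.48), Fkbp4 (0.41 ± 0.09) and Hspa1a (0.63 ± 0.21). When adjusted over the list alone 12 were higher and 2 lower, Hsph1 (-0.23 ± 0.09) and Dnajb5 (-0.44 ± 0.17). On vehicle the heat shock list gave adjusted p = 0.00109, but adjusted p = 0.201 with an estimated correlation. The call of Hspa1a was lost without R6/2 vehicle replicate 7 (adjusted p = 0.0744) and without wild-type vehicle replicate 1 or 6 (0.0606 and 0.0743). That of Hspd1 was lost without R6/2 vehicle replicate 6 or wild-type vehicle replicate 1 or 2 (0.0501, 0.0553 and 0.0511), and that of Dnaja1 without R6/2 vehicle replicate 4 or 6 (0.0588 and 0.0647). In a fit of the vehicle groups alone the calls of Hspa1a, Dnaja1 and Hspa8 were lost (0.109, 0.0741 and 0.062), and with the mean of the probe sets of a gene those of Fkbp4 and Dnajb6 (0.256 and 0.0992). Of 19 co-chaperone and chaperonin genes 8 were higher, such as Cct8 (0.59 ± 0.12) and Cct2 (0.36 ± 0.06), and 12 were when adjusted over the list alone (adjusted p = 9.55e-05, but adjusted p = 0.0695 with an estimated correlation). Cholesterol synthesis genes were lower in 6 of 20 cases (7 when adjusted over the list alone), with Insig1 at -0.75 ± 0.15 and Fdft1 at -0.63 ± 0.12 (adjusted p = 0.00205, but adjusted p = 0.201 with an estimated correlation). Chromatin genes of the histone list were higher in 7 of 20 cases, as Sirt1 (0.61 ± 0.12) and Hdac1 (0.43 ± 0.10), and H2ax was lower (7 higher and 2 lower when adjusted over the list alone). The histone list gave adjusted p = 0.0283, but adjusted p = 0.201 with an estimated correlation. Its call was lost without R6/2 vehicle replicate 1 (0.0815) or wild-type vehicle replicate 7 (0.066).

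In total 3906 genes differed on vehicle, 2160 higher and 1746 lower in R6/2, of which 24 were higher and 170 lower by at least 2-fold. The largest falls beside Scn4b were in Abi3bp (9.14-fold, log2 -3.19 ± 0.33), Crh (6.14-fold, -2.62 ± 0.51), the calcium release channel gene Ryr1 (5.48-fold, -2.45 ± 0.23), Syndig1l (5.41-fold), Car12 (5.11-fold), Sdr39u1 (4.76-fold), Phex (4.55-fold), Dmkn (4.43-fold) and Lrrc10b (4.36-fold). The largest rises were in Sfmbt2 (3.74-fold, 1.90 ± 0.22), the protocadherin gene Pcdh20 (3.5-fold, 1.81 ± 0.26), Tdo2 (3.26-fold, 1.70 ± 0.63), the transcription factor gene Pou4f1 (3.05-fold, 1.61 ± 0.29), Insyn2b (2.7-fold), Zfhx2os (2.51-fold), Pcdh19 (2.47-fold), the cell cycle kinase subunit genes Cks1b (2.34-fold) and Cks2 (2.25-fold), and Baiap3 (2.21-fold, 1.15 ± 0.34). All 7 R6/2 arrays lay beyond the wild-type mean for each of these genes except Tdo2, with 6 of 7. These genes were chosen on the same arrays, and the genotypes did not overlap for 5 of the 10 largest rises and 9 of the 10 largest falls. Abi3bp, Crh, Phex, Insyn2b, Pou4f1, Tdo2, Zfhx2os, Th and Slc18a3 are dim genes. The call of Tdo2 (adjusted p = 0.0498) was lost with the removal of any of 24 arrays (0.0502 to 0.145).

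Microglia markers were lower in R6/2 on vehicle in 4 of 15 cases, Aif1, C1qb, C1qc and Cd68, and Ctss was higher (the same counts when adjusted over the list alone; adjusted p = 0.0141, but adjusted p = 0.201 with an estimated correlation). Astrocyte (Aldh1l1, Atp1b2 and Ntsr2) and myelin genes (Fa2h, Mobp and Mal) had 3 lower members of 15 and 14 (the same when adjusted over the list alone; adjusted p = 0.0399 and 0.0468, but adjusted p = 0.397 and 0.601 with an estimated correlation). These calls were lost with the removal of any of 6 and 7 arrays (0.0515 to 0.199 and 0.0534 to 0.251). Respiratory chain genes were higher in 6 of 32 cases and Sdhc was lower (the same when adjusted over the list alone; adjusted p = 0.0146, but adjusted p = 0.397 with an estimated correlation). Of the glucocorticoid-responsive genes 5 of 24, Klf9, Per1, Sgk1, Hif3a and Mfsd2a, were lower over all genes and over the list alone (adjusted p = 0.00205, but adjusted p = 0.45 with an estimated correlation). This list call was lost without wild-type vehicle replicate 4 (0.139), where 3 members were lower and 1 higher and the mean log2 difference went from -0.28 to -0.12. The choroid plexus list was lower with none of 15 members past the test in either count (adjusted p = 0.0125, but adjusted p = 0.503 with an estimated correlation, and 0.0803 without wild-type vehicle replicate 4).

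On HSP990 the comparison of R6/2 with wild-type mice describes the genotype difference in treated animals. Medium spiny neuron genes were again lower, with Scn4b at 9.07-fold (log2 -3.18 ± 0.23, SE, n = 8 and 10 arrays), Drd1 at 4.4-fold (-2.14 ± 0.14), Rgs9 at 4.12-fold (-2.04 ± 0.17) and Adcy5 at 2.95-fold (-1.56 ± 0.13). Of 27 members 25 were lower (26 when adjusted over the list alone; adjusted p = 1.06e-31, and adjusted p = 0.0118 with an estimated correlation). Synaptic channel and receptor genes were lower in 21 of 25 cases over all genes and over the list alone (adjusted p = 1.12e-17, and adjusted p = 0.00145 with an estimated correlation), among them the glutamate receptor gene Grm5 (-0.85 ± 0.09). Immediate early genes were lower in 14 of 26 cases in both counts, with Egr2 at -2.16 ± 0.30 and Egr3 at -1.32 ± 0.11 (adjusted p = 1.87e-08, and adjusted p = 0.0458 with an estimated correlation). Clock genes were lower in 10 of 18 cases, with Npas2 at -1.68 ± 0.09, and Cry1 and Nfil3 were higher (12 lower and 2 higher when adjusted over the list alone; adjusted p = 2.16e-06, and adjusted p = 0.00667 with an estimated correlation). Interneuron markers were lower in 8 of 14 cases in both counts, with Slc18a3 at -0.87 ± 0.11 (adjusted p = 0.000101, and adjusted p = 0.00337 with an estimated correlation).

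Of 27 heat shock genes 9 were lower in R6/2 on HSP990, among them Hspa1a (log2 -0.98 ± 0.18), Hsph1 (-0.65) and Hspe1 (-0.56 ± 0.07), and Ahsa2 was higher (0.62 ± 0.11). When adjusted over the list alone 11 were lower and 3 higher (adjusted p = 0.00589, but adjusted p = 0.307 with an estimated correlation). Of the 9 only Hspa1a and Hspd1 had been called higher on vehicle, calls that single arrays could end. On HSP990 the call of Cryab was lost without R6/2 HSP990 replicate 6 or wild-type HSP990 replicate 2 (0.0508 and 0.0512). The call of Hspa4l was lost without R6/2 HSP990 replicate 2, 4 or 5 (0.0604, 0.0618 and 0.0766), with array weights (0.0735), with the 3' covariate (0.249) and without the 2 arrays of strong 3' bias (0.0796). St13 did not pass with the mean of its probe sets (0.0506). Proteasome subunits were higher in 19 of 31 cases, as Psma5 (0.43 ± 0.04), and 20 higher and 1 lower when adjusted over the list alone (adjusted p = 3.28e-05, but adjusted p = 0.159 with an estimated correlation). Respiratory chain genes were higher in 16 of 32 cases in both counts, as Sdha (0.52 ± 0.06; adjusted p = 0.000709, but adjusted p = 0.245 with an estimated correlation). Myelin genes were lower in 8 of 14 cases, as Ugt8a (-0.93 ± 0.17), and 9 when adjusted over the list alone (adjusted p = 9.62e-05, but adjusted p = 0.307 with an estimated correlation). Astrocyte markers were lower in 9 of 15 cases and S100b was higher (10 lower and 1 higher when adjusted over the list alone; adjusted p = 0.000928, but adjusted p = 0.16 with an estimated correlation). Microglia markers were lower in 6 of 15 cases in both counts, as Cx3cr1 (-0.49 ± 0.11; adjusted p = 0.0108, but adjusted p = 0.211 with an estimated correlation). Cholesterol synthesis genes went both ways, 7 of 20 lower, as Msmo1 (-1.12 ± 0.18), and Hsd17b7, Pmvk and Tm7sf2 higher, in both counts. The cholesterol list gave adjusted p = 0.0472, but adjusted p = 0.446 with an estimated correlation, and was lost with the removal of any of 9 arrays (0.0503 to 0.0765).

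In total 6108 genes differed on HSP990, 4110 higher and 1998 lower in R6/2, of which 81 were higher and 221 lower by at least 2-fold. The largest rises were in Pou4f1 (5.9-fold, log2 2.56 ± 0.25), Sfmbt2 (4.33-fold), Cks2 (4.23-fold), Cks1b (3.59-fold) and Insyn2b (3.17-fold). The largest falls beside Scn4b were in Ryr1 (7.98-fold, -3.00 ± 0.20), Wnt8b (7.23-fold), Ano3 (6.77-fold) and Phex (6.29-fold). All 8 R6/2 arrays lay beyond the wild-type mean for each of these genes, of which Phex, Wnt8b, Insyn2b and Pou4f1 are dim, as are Egr2 and Slc18a3. The genotypes did not overlap for all 5 rises and all 5 falls, genes chosen on the same arrays. The genotype differences on vehicle and on HSP990 shared 1769 higher and 1180 lower genes (488 and 192 for independent lists), with 3 and 6 genes in opposite directions, and correlated with r = 0.792 across all genes. Here too the shared estimate of the spread makes independent lists a low baseline.

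Htt, the mouse huntingtin gene, and Hsf2, a heat shock factor gene, did not pass in any of the 5 comparisons. Their adjusted p were 0.795 and 0.187 for HSP990 in wild type, 0.345 and 0.95 for HSP990 in R6/2, 0.753 and 0.944 for genotype on vehicle, 0.603 and 0.0724 for genotype on HSP990, and 0.735 and 0.577 for the interaction, with log2 changes between -0.25 and 0.27. The Htt probe sets were designed on the mouse gene and say nothing about the level of the transgene. Hsf2 is a dim gene (mean value 5.17), so a change in its level could be missed.

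The remaining lists were not called in any comparison. Oligodendrocyte precursor markers had at most 1 of 8 members past the test in each direction (at most 2 when adjusted over the list alone), and markers of the neighbouring cortex at most 2 of 14 lower in both counts, Lamp5 and Lmo4 on HSP990. Endothelial markers had 1 higher and 1 lower member with HSP990 in wild type, Flt1 (0.39 ± 0.07) and the glucose transporter gene Slc2a1 (-0.83 ± 0.11), of 14 measured (2 and 2 when adjusted over the list alone). With HSP990 in R6/2 they had 1 higher and 1 lower, and for genotype on vehicle 1 lower, in both counts. For genotype on HSP990 1 was higher and 2 were lower, but none when adjusted over the list alone. Red blood cell transcripts had 1 lower member of 4, Alas2, in both genotype comparisons and both counts. Among markers of neighbouring subcortical regions, Baiap3 was higher in R6/2 on vehicle and Trh, Gbx1, Calcr and Lhx8 were lower, of 14 measured, in both counts. Trh, Gbx1, Calcr and all 4 red blood cell transcripts are dim, so their changes are less certain and others could be missed. The SD between arrays of the mean of the cortex and choroid plexus lists was large beside that of other lists, 0.83 for the choroid plexus list in R6/2 on HSP990 against 0.31 for medium spiny neuron genes.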

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

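Chosen only after the results were seen were the tests of the 2 arrays of strong 3' bias, of the level on vehicle, of the response of genes outside the chaperone lists, of the share of medium spiny neurons and of cortex in the dissections. The test of a list of DNA replication and mitosis genes and the random splits of the arrays were set up before their values were seen.

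The response of the heat shock list was smaller in R6/2 than in wild type, with a slope of 0.760 (95% interval 0.668 to 0.855). Without the 2 arrays of strong 3' bias it was 0.766 (0.667 to 0.865), which argues against degraded RNA in those arrays as the cause. A higher level on vehicle alone does not account for the mean over the list. On HSP990 the same 22 genes were lower in R6/2 by a mean log2 difference of -0.20 (-0.30 to -0.09). On vehicle they had been higher by 0.24 (0.13 to 0.34). For single genes it may account. Ahsa2, Dnajb1, Ahsa1, Hspa8, Hspa9, Fkbp4 and Hsp90aa1 were not lower in R6/2 on HSP990, with differences from 0.62 (Ahsa2) to 0.0084 (Hsp90aa1). The other members of the 22 had negative differences. A smaller response of all drug-induced genes cannot be told apart from one of the heat shock list alone. A slope falls below 1 from noise in the wild-type changes, so genes outside the heat shock and co-chaperone lists were chosen and weighted in 1 part of the arrays and measured in the other part, over 50 random divisions. Their ratio was 0.850 (0.610 to 1.09), an interval that holds both 1 and the ratio of 0.771 (0.668 to 0.874) of the 27 heat shock genes by the same method. These intervals hold the choice of genes fixed. For genes that fell the ratio was 0.583 (0.264 to 0.901), under 1, which goes with a smaller response in general but does not cover genes that rose. An earlier test, the slope over 695 genes that rose in the averaged response, gave 0.788 (0.599 to 0.903) and had been read as fitting a smaller general response. It was replaced after that value was seen, because noise alone can bring such a slope under 1. Less drug in the R6/2 striatum or a change in the cells could each lie behind the smaller heat shock response, and neither was measured here.

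Medium spiny neuron genes were lower in R6/2 on vehicle. A smaller share of these neurons, if nothing else changed, would leave markers of other striatal cells level or higher. The interneuron list was lower by a mean log2 difference of -0.39 (-0.54 to -0.23) and the microglia list by -0.27 (-0.38 to -0.15). Those cells may have changed for reasons of their own, so the test cannot decide why medium spiny neuron genes fell. The intervals of the other 4 lists tested reached 0: astrocyte (-0.38 to 0.03), myelin (-0.59 to 0.07), oligodendrocyte precursor (-0.23 to 0.19) and endothelial (-0.14 to 0.05). The interneuron and endothelial lists moved apart by more than their intervals, but this pair was picked after the values were seen. The interneuron list also holds dim genes such as Slc18a3 and Th, so no conclusion is drawn from the pair. The interneuron and microglia intervals below 0 argue against a smaller share of medium spiny neurons as the only difference in the tissue. More cortex in the R6/2 dissections cannot be told apart from none, since the cortical list differed by 0.0059 with an interval from -0.73 to 0.76. A loss of medium spiny neurons, partial or as the whole cause of their lower genes, and lower expression within them all remain open. The arrays of whole tissue do not separate them.

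Of the 45 genes of the interaction, 31 had a higher change in R6/2, with a mean interaction of 0.63 log2 units. Without the 2 arrays of strong 3' bias 14 of the 31 were still called higher, which for these genes argues against degraded RNA in those arrays as the whole cause. For the other 17 it cannot be told apart: their mean interaction went from 0.57 (0.47 to 0.67) to 0.53 (0.44 to 0.62), but they had been chosen for a high value with those arrays included. Their calls ended with this lower mean, at a mean SE of 0.123 before and 0.124 after. The group means of the 3' bias themselves moved apart with HSP990. The Actb difference went from 1.76 to 2.32 in R6/2 and from 2.00 to 1.62 in wild type. That of Gapdh went from 0.53 to 1.34 and from 0.83 to 0.47. These means include the 2 arrays of strong 3' bias, which enlarge the shift. Gapdh was at 5.01 in R6/2 HSP990 replicate 5, against 0.26 to 1.53 in the others of its group. In wild-type vehicle replicate 5 it was at 2.23, against 0.23 to 1.07. With the 3' bias of each array as a covariate 8 of the 31 were called higher, with a mean interaction of 0.55 for all 31, and 14 of the 45 genes were called among 16 in all. Because Cenpe, Rad51ap1 and Chek1 act in cell division and DNA repair, a hypothesis was that genes of DNA replication and mitosis as a class rise more in R6/2. In a list of 46 measured such genes, without those seen to be called, the list test with an estimated correlation gave p = 0.0541 and with the preset correlation p = 1.88e-05. The bound set in advance counted p of 0.05 or more against the hypothesis, and this value lay narrowly on that side. That bound was wrong, since a p above a threshold does not show absence and a list without the called genes excludes nothing. The hypothesis therefore stays open, a reading that was changed after the value was seen.

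Chance was examined with 100 splits of the arrays for each comparison, the real split included. For HSP990 in wild type the real split (1056 genes) was the 1 split of 100 with as many genes, and the highest other split gave 2. The same held for HSP990 in R6/2 (563 genes, highest other 172), for genotype on vehicle (3906, highest other 1200) and for genotype on HSP990 (6108, highest other 8). For the interaction, 3 of 100 rearrangements of the residuals gave at least 45 genes, the real arrangement included. The highest others gave 393 and 140, several times the real count, which points to structure among the arrays beyond the groups.

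In 120 groups of arrays (array quality measures, the 23 list means and 5 genes; the other named genes were not looked at in this way) 11 values from 8 arrays stood apart, where chance gives about 1 in 20 groups. The difference between 3' and 5' probe sets of Gapdh was 5.01 in R6/2 HSP990 replicate 5, 2.23 in wild-type vehicle replicate 5 and 1.46 in R6/2 vehicle replicate 1, and that of Actb was 2.76 in R6/2 vehicle replicate 1. The mean of the glucocorticoid-responsive list was 9.56 in wild-type vehicle replicate 4, against 8.14 to 8.58 in the others. The mean of the cholesterol list was 8.23 in R6/2 HSP990 replicate 6, that of the medium spiny neuron list was 10.996 in wild-type HSP990 replicate 6, and that of the choroid plexus list was 8.62 in wild-type HSP990 replicate 2. Without this array the choroid plexus list was called lower for HSP990 in wild type (mean -0.73, adjusted p = 0.0094, against -0.47 and 0.227 with it). It was also called higher for the interaction (1.01, 0.00682, against 0.74 and 0.167), though neither held with an estimated correlation (adjusted p = 0.577 and 0.727). On HSP990 its mean genotype difference, not called, went from -0.07 to 0.19. In R6/2 vehicle replicate 7 Hspa1a was at 7.82 and Hspa1b at 9.52, and in R6/2 vehicle replicate 1 Htt was at 9.01.

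The response to HSP990 differed between the genotypes, by the test of the interaction, for Cenpe (0.88), Mknk2 (0.60), Kcns2 (-0.74), Hspe1 (-0.68), Sap30 (0.74), Tcf19 (1.06), Hspa1a (-1.61), Rad51ap1 (0.93), Hspd1 (-0.67) and Chek1 (0.66). Lists with a different response were the heat shock (adjusted p = 6.55e-19), co-chaperone (1.86e-05), immediate early (0.00391), myelin (0.00391), synaptic (0.00391), medium spiny neuron (0.00988) and unfolded protein response (0.00988) lists. With an estimated correlation only the heat shock list held (adjusted p = 0.00271).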

How the results depend on the processing

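No called result for a named gene changed direction under any alternative run on it. Some alternatives could not change a direction, because they leave the log2 change as it is. These were removal of dim probe sets, only the groups compared, the trended and robust variance and the residual component. The fit of all probe sets was not run on named genes. The size of the heat shock response in R6/2 relative to wild type ran from 0.641 to 0.771 over its alternatives other than single arrays. Neither end is a slope: 0.641 is the median of the ratios of the 22 members, and 0.771 is the ratio from separate parts of the arrays. With each array left out the slope ran from 0.737 to 0.790. Each of these intervals was under 1. The alternatives with 3' bias or without its 2 arrays, the slope over members called for the averaged response, and the ratio from separate parts of the arrays (0.771, 0.668 to 0.874), were chosen after seeing the data. With a residual component as a covariate 1699 genes were called for HSP990 in wild type, 1100 for HSP990 in R6/2 and 398 for the interaction. This component is taken from the residuals of the same fit, so it narrows the spread and leaves the log2 changes as they are. Higher counts follow from its construction and say nothing for or against the calls. With array weights 1815 were called in wild type and 150 for the interaction. With all probe sets, where more features are tested, 2087, 1267, 6795, 12261 and 122 were called in the order wild type, R6/2, genotype on vehicle, genotype on HSP990 and interaction. With the mean of the probe sets 80 genes passed the interaction test, of which 28 were among the 45. With only the groups compared 202 were called in R6/2. With the 3' covariate 368 were called in R6/2 and 16 for the interaction, and without the 2 arrays of strong 3' bias 25 for the interaction, with 11 lists. With each array left out the counts were 768 to 1194 in wild type, 309 to 1043 in R6/2, 3281 to 4379 on vehicle, 5740 to 6305 on HSP990 and 30 to 182 for the interaction. The lists called, 8, 5, 16, 12 and 7 in that order, numbered 2, 2, 5, 5 and 1 with an estimated correlation, and 3 in R6/2 and 1 for the interaction with fry, and 6 to 10, 4 to 9, 13 to 16, 11 to 13 and 5 to 11 with each array left out. Apart from the residual component, the cause of these changes was not tested. The labels do not say that replicate numbers pair the arrays. Correlations of arrays with the same number ran from -0.22 to 0.38, over 0.1 in 3 of 7 pairs for HSP990 in wild type, 2 of 7 in R6/2, 5 of 7 for genotype on vehicle and 3 of 8 on HSP990. At most 3 arrays of a comparison correlated best with their own number. With replicate number as a block 655 genes were called in wild type and 23 for the interaction, while the 586, 3782 and 5596 genes of the other comparisons were within 1.5 times. Of 623 results for named genes, 598 kept their side of the threshold with the block. On probe sets above the median mean of 5.77, 504 of 524 results for named genes kept their side. The results for dim genes, at or below it, are not covered by this.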

Other observations

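Of 46 measured genes of DNA replication and mitosis, a list written after the interaction genes had been seen, 22 were higher in R6/2 than in wild-type mice on HSP990, 3 were lower and 21 did not pass. The list test gave p = 0.00114 with the preset correlation, but p = 0.138 with an estimated correlation. Higher were the replication genes Mcm2, Mcm4, Pcna and Rrm1, among others, and lower were Melk, Ccna2 and Plk1. On vehicle Rrm1, Mcm6, Pcna, Rfc4 and Smc2 were higher and the same 3 genes were lower. The list test on vehicle gave p = 0.635 and, with an estimated correlation, p = 0.825. With HSP990 in R6/2 only Mcm5 passed as higher, with a mean log2 change of the list of 0.13 (p = 0.000167, but p = 0.0879 with an estimated correlation). In wild type Fen1 and Ccne1 passed as lower, with a mean of -0.07 (p = 0.182, and p = 0.536 with an estimated correlation). These genes were named after their values were seen.

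The slope of the R6/2 response on the wild-type response depended on how genes were chosen. Genes chosen in wild type gave 0.565 (95% interval 0.432 to 0.659) for those that rose outside the heat shock list and 0.346 (0.182 to 0.479) for those that fell. Genes chosen in R6/2 gave 0.953 (0.764 to 1.05) and 0.911 (0.654 to 1.10), with median ratios of 1.41 and 1.31. Genes chosen for the response averaged over both genotypes gave 0.788 (0.599 to 0.903) for 695 that rose outside the heat shock and co-chaperone lists and 0.611 (0.403 to 0.770) for 674 that fell. With genes outside those lists chosen in 1 part of the arrays and measured in the other part, the ratio was 0.850 (0.610 to 1.09) for rises and 0.583 (0.264 to 0.901) for falls.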
